A study of Mus musculus with 8 samples.

How the data were processed

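RNA was extracted from whole mouse hearts with Trizol, and Illumina libraries from polyadenylated RNA were sequenced by a commercial provider, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for 8 libraries, with no normalization, and the gene identifier, symbol, biotype, length and coordinates of 56748 genes. The submitters' processing notes name CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1, and the builds mm10 and GRCm38.p6, without giving the role of each; whether the counts used strand, and how reads that match several genes were treated, is not given in the sources used here. The coordinates in the deposited table equal those of GENCODE M21, an annotation of GRCm38, for 1524 of 52125 genes matched by identifier (2.92%), so the table follows another build or release than the notes name. Coordinates are therefore printed as the deposited table gives them, with the build unsettled. Without strand information, reads of overlapping and antisense genes cannot be told apart. Smad7 and its neighbour Gm20544 lie next to each other on opposite strands.

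Groups were taken from the labels, with 4 CRE and 4 CS7KO libraries. Total counts were 21581878, 19779286, 29751644 and 16476420 in CRE 1, 2, 3 and 5 and 22376432, 19786249, 40181492 and 16679724 in CS7KO 1 to 4. At these depths 3 counts, the limit that a count of 0 allows, came to between 0.064 and 0.363 CPM; intervals and floors cover counting error only. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 9.58 in every pair, so no library was counted as a duplicate.

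Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on genotype (minimum count 10, minimum total 15), which left 16002 genes, libraries were scaled by TMM, and a robust quasi-likelihood model with genotype and labelled sex was fitted. P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 counted as passing. Fold changes are CS7KO over CRE, standard errors were taken from the fold change and its F statistic, and CPM values use the TMM-scaled library sizes. The interaction of genotype and labelled sex was tested in a model of 4 groups of 2 libraries. Values compared once between the genotypes used exact permutation tests over all 70 assignments of the 8 libraries, counting differences in both directions.

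The gene lists, the rule for named genes and most other settings were fixed before the data were examined. Of 59 lists of cardiac, matrix, signalling, metabolic, immune and cell type marker genes, 57 had at least 5 tested members; those of thymus and lung epithelium had too few. Lists were compared with all other genes by camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, then with the correlation estimated. By fry each list was tested against no change, in 1 direction and in either. Members were also adjusted over the list alone. A list's median in a library is the median of log2 CPM (prior count 2) minus each gene's mean over the 8 libraries.

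Named genes followed this rule: Smad7; the genes that passed in both directions, with all 4 libraries of a group on one side, a mean of at least 1 CPM and a plain symbol, or, as fewer than 12 did, the 12 such genes with the smallest p as values; a set of anchors of TGF-beta signalling, matrix and hypertrophy; up to 4 passing members of each list, or the 2 with the smallest p; the 3 interaction genes with the smallest p; and Xist and the Y-linked genes. For length, members of lists that did not pass, and some of those that did, are left out. Gm8730, Gm9625, Gapdh, Rplp0, Rpl30 and Rps3a1 were named after their values were seen.

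Near-identical copies were found by aligning the M21 transcripts of the passing genes, and of their protein-coding parents, to all M21 transcripts with blastn 2.17.0, and families were formed at 90% identity over at least 100 bases. M21 was used for sequence only. The edgeR and camera tests of genotype were run on simulated counts drawn from the means and spread of the 8 libraries. There 36 of 100 genes changed 4-fold and 4 of 100 changed 2-fold were recovered in the right direction, and 2 of 15782 unchanged genes were called. A list shifted 2-fold was called with no other. Genes were drawn independently of each other, so this does not show how camera behaves when list members are correlated. In the data that correlation was estimated at 0.846 for TCA cycle genes and 0.888 for nuclear-encoded oxidative phosphorylation. The other settings were DESeq2 1.42.0, limma-voom, other size factors, no filter or a strict one (1 CPM in 4 libraries), no term for labelled sex, a block for the replicate number, each library left out in turn, an adjusted p under 0.1, a minimum of 1.5-fold, protein-coding genes alone, and removal of mitochondrial and the 10 most counted genes. Settings added after the data were seen left out CRE 1 and CRE 5, or CRE 3 and CRE 5, used sample quality weights, or dropped the term for labelled sex together with either pair. The plots were drawn with matplotlib 3.10.9.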

Results

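Whole mouse hearts were compared 56 days after transverse aortic constriction, a surgical narrowing of the aortic arch that loads the left ventricle with pressure. CS7KO hearts came from mice in which Smad7, an inhibitory Smad that restrains TGF-beta receptor signalling, was deleted in cardiomyocytes by a Cre recombinase under the alpha myosin heavy chain promoter. CRE hearts, with that Cre alone, were the control. Each heart gave 1 RNA sequencing library, with 4 CRE libraries (numbered 1, 2, 3 and 5) and 4 CS7KO libraries (numbered 1 to 4). In each genotype 2 hearts were labelled male and 2 female, and the series design describes the samples as independent. Total counts ranged from 16476420 in CRE 5 to 40181492 in CS7KO 3.

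The CRE libraries differed more among themselves than the CS7KO libraries did. The mitochondrially encoded genes took 15.04%, 20.3%, 41.1% and 69.8% of the counts in CRE 1, 2, 3 and 5, and between 20.2% and 24.9% in the CS7KO libraries, with group means of 36.6 ± 24.9% and 21.9 ± 2.23% (SD, n = 4 each; exact permutation test on both sides, p = 0.371). CRE 1 had 537 genes with 1 to 9 counts, against 5848 to 19697 in the other libraries. The first principal component, with 51.2% of the variance, set CRE 1 apart from the rest, and the second, with 27.3%, set CRE 5 apart. Log2 CPM in CRE 2 correlated across genes with the CS7KO libraries at a mean r of 0.962 and with its own group at 0.896 (genes are not independent replicates). Gapdh, a glycolytic enzyme often used as a reference and singled out here after its values were seen, had 724.6, 9.16, 230.2 and 11.6 CPM (counts scaled to the library's size) in CRE 1, 2, 3 and 5 and 8.81, 9.78, 106.6 and 9.07 CPM in CS7KO 1 to 4, so CS7KO 3 stood apart in its group too. Whether all libraries were prepared and counted alike is not given in the sources used here.

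**Figure D1:**
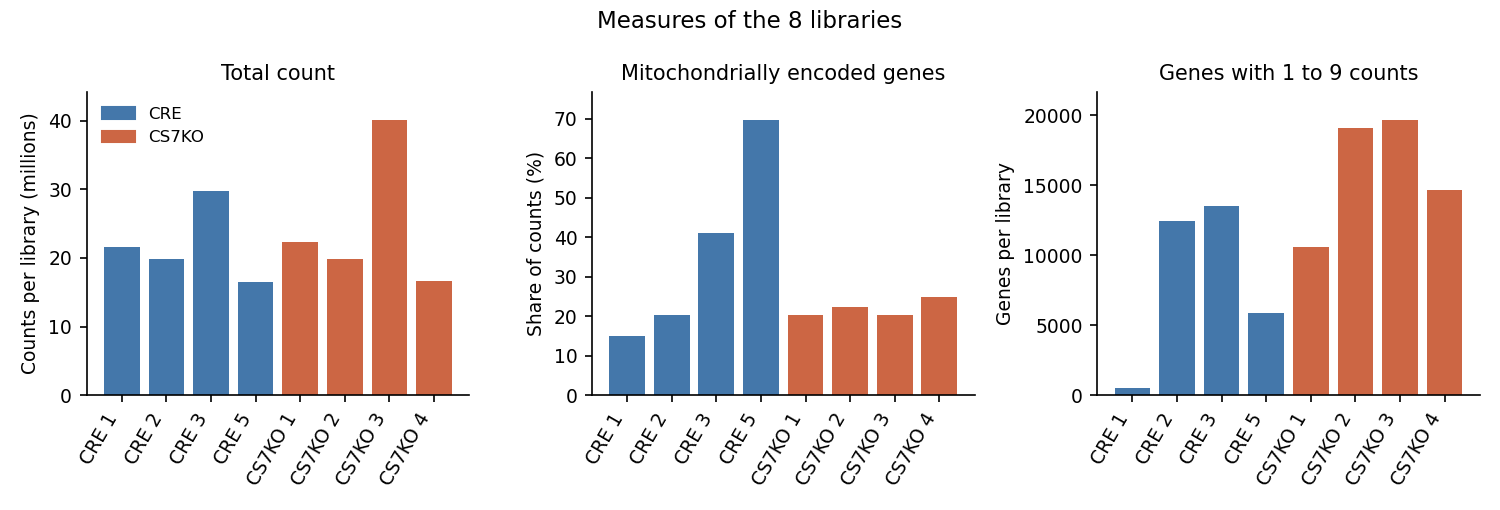
Bars give, for each of the 8 libraries, the total count (an axis value of 21.6 for the 21581878 counts of CRE 1), the share of counts in mitochondrially encoded genes in percent and the number of genes with 1 to 9 counts, with CRE in blue and CS7KO in orange. CRE 5 had the highest mitochondrial share (69.8%) and CRE 1 the fewest genes with 1 to 9 counts (537).

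Smad7, the deleted gene (ENSMUSG00000025880), was measured first, as the check on the genotype labels. It stood at 17.6, 25.5, 25.2 and 45.4 CPM in CRE 1, 2, 3 and 5 and at 19.8, 13.3, 27.8 and 12.3 CPM in CS7KO 1 to 4, with means of 28.4 ± 11.9 and 18.3 ± 7.14 CPM (SD, n = 4 each). The log2 fold change of CS7KO over CRE was -0.59 (SE 0.34, 95% interval -1.36 to 0.17, edgeR adjusted p = 0.509). The interval includes no change, and the values of the groups overlapped. The deposited table places the gene on chromosome 18, from 75500600 to 75529006 on the plus strand, and counts reads over the whole gene, so RNA from other heart cells and from exons left in place would enter the same value. Smad7 therefore neither bore out nor contradicted the genotype labels. Among 18 tested genes around Smad7 on chromosome 18, 10 lay higher and 8 lower in CS7KO, and the list did not pass (camera adjusted p = 0.582). Its smallest p was that of Gm20544, the neighbour on the opposite strand, with 9.15 ± 5.92 CPM in CRE and 2.27 ± 1.55 in CS7KO. That gene did not pass (log2 -2.01, SE 0.54, edgeR adjusted p = 0.291), though its libraries separated by genotype.

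The main question, which genes differ between pressure-overloaded hearts with and without Smad7 in cardiomyocytes, gave 3 genes that rose and 3 that fell in CS7KO among 16002 tested (edgeR adjusted p under 0.05). Pttg1, which encodes securin, the inhibitor of separase that is destroyed at anaphase, rose from 6.01 ± 2.24 CPM in CRE to 47.7 ± 9.41 in CS7KO (8.00-fold; log2 fold change 3.00, SE 0.34, adjusted p = 0.0196). Cyfip2, a subunit of the WAVE complex that controls actin assembly, rose from 21.6 ± 7.94 to 115 ± 18.2 CPM (5.43-fold; log2 2.44, SE 0.31, adjusted p = 0.0390). Both lie on chromosome 11 in the deposited table, Pttg1 from 43311077 to 43317078 and Cyfip2 from 46084677 to 46203686. The third gene that rose was Rps3a2, a processed pseudogene of the ribosomal protein gene Rps3a1, from 2.06 ± 0.523 to 47.8 ± 6.58 CPM (23.6-fold; log2 4.56, SE 0.30, adjusted p = 4.7e-04). In each of the 6 genes all 4 CS7KO libraries lay on one side of all 4 CRE libraries, a separation shown by 1655 of the 16002 genes (10.3%). The mean over all assignments of the libraries is 2.86%. Genes move together, so a single assignment can lie far from that mean, and the spread was not tested.

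The 3 genes that fell were also processed pseudogenes of ribosomal protein genes. Rpl30-ps10 fell from 13.3 ± 7.29 to 0.901 ± 0.127 CPM (log2 -3.73, SE 0.45, adjusted p = 0.0285). Gm8730 fell from 144 ± 85.7 to 2.02 ± 0.603 CPM (log2 -6.13, SE 0.43, adjusted p = 5.4e-04) and Gm9625 from 18.6 ± 11.5 to 0.173 ± 0.0637 CPM (log2 -6.55, SE 0.55, adjusted p = 0.00203). Gm8730 and Gm9625 fall outside the rule for named genes and were named after their values were seen. The 4 pseudogenes are near-identical to other genes, so a read can match more than 1 of them, and their counts are uncertain for that reason. Over their whole length Gm8730 and Gm9625 matched the Rplp0 transcript at 98.7% and 97.4% identity, Rpl30-ps10 matched Rpl30 at 99.1% and Rps3a2 matched Rps3a1 at 99.5%. Gm8730 took 20.05 ± 1.201% of the counts of Gm8730 and Rplp0 in CRE and 0.309 ± 0.104% in CS7KO, while the summed counts of Rplp0 and its copies differed by -0.05 on the log2 scale (95% interval -0.90 to 0.79). Rps3a2 took 0.301 ± 0.101% of the counts of Rps3a2 and Rps3a1 in CRE and 10.6 ± 0.475% in CS7KO. The summed counts of Rps3a1 and its copies differed by -0.69 (95% interval -1.47 to 0.098). Those of Rpl30 and its copies differed by -1.16 (95% interval -1.91 to -0.42, edgeR adjusted p = 0.293). With each such family summed to 1 value, 0 of 15992 genes passed edgeR's test, and 2015 had an unadjusted p under 0.05. Pttg1 then had an adjusted p of 0.0786 and Cyfip2 of 0.116, at the same log2 fold changes of 3.00 and 2.44. Their standard errors also stayed at 0.34 and 0.31. The adjusted values rose because the pseudogenes that had ranked ahead of both genes were no longer counted as separate genes. Pttg1 and Cyfip2 thus passed only in a ranking that held those pseudogenes, and their own measured change did not weaken.

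**Figure D2:**
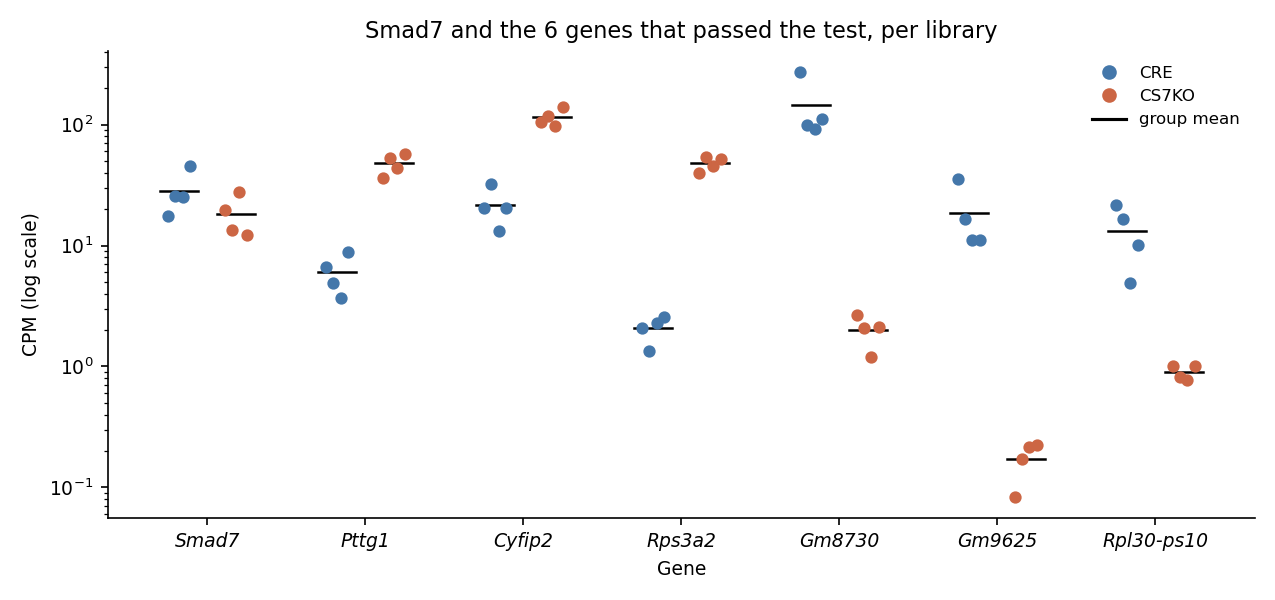
Points give CPM (log scale) of Smad7 and of the 6 genes that passed the test in each of 4 CRE (blue) and 4 CS7KO (orange) libraries, and black lines give the group means. The groups overlap for Smad7 and are apart for the other genes, for example Pttg1 with means of 6.01 and 47.7 CPM.

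**Figure D3:**
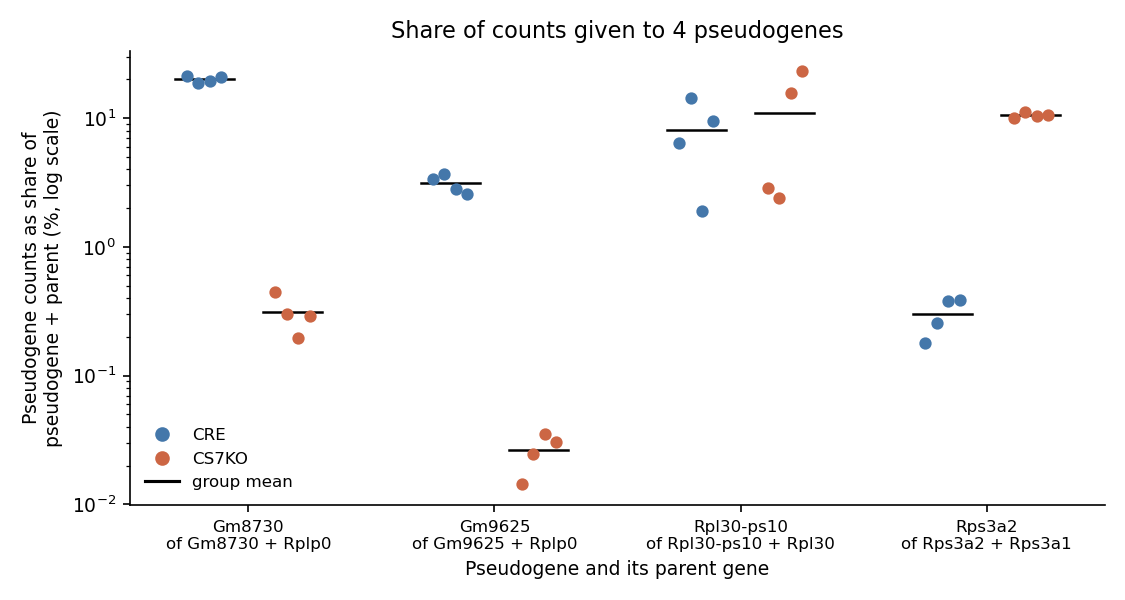
Points give the counts of a pseudogene as a share, in percent on a log scale, of the counts of the pseudogene and its parent gene in each CRE (blue) and CS7KO (orange) library, and black lines give the group means. Gm8730 took 20.05% in CRE and 0.309% in CS7KO on average, Rps3a2 took 0.301% and 10.6%, and the groups overlap for Rpl30-ps10.

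Rps3a2, Gm8730 and Gm9625 passed whichever single library was left out. Cyfip2 did not pass without CRE 1 (adjusted p = 0.0581), CRE 3 (0.272), CRE 5 (0.146), CS7KO 1 (0.105), CS7KO 2 (0.0952), CS7KO 3 (0.131) or CS7KO 4 (0.0796). Pttg1 did not pass without CRE 2 (0.0575), CRE 3 (0.0549), CS7KO 2 (0.0784) or CS7KO 3 (0.0629). Rpl30-ps10 did not pass without CRE 2 (0.0575), CRE 5 (0.102), CS7KO 1 (0.178), CS7KO 2 (0.0952) or CS7KO 3 (0.131). Their log2 fold changes stayed between 2.02 and 2.67 for Cyfip2, 2.78 and 3.51 for Pttg1, and -4.45 and -3.04 for Rpl30-ps10 over all alternatives. The count of genes was 14 without CRE 1 and 3 without CS7KO 3. DESeq2 called 503 genes and limma-voom 5, and 2022 genes (12.6%) had an unadjusted p under 0.05 in edgeR.

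Of the protein-coding genes with the next smallest p, none passed edgeR's test, while DESeq2 called all 8 named here (adjusted p from 4.6e-09 to 1.2e-05). Myct1, a target of the Myc oncoprotein, stood at -2.40 (SE 0.32, adjusted p = 0.0553) on the log2 scale. Aplnr, the receptor of the vascular peptide apelin, was at -2.22 (SE 0.33, adjusted p = 0.110) and Hlx, a homeobox transcription factor, at -2.07 (SE 0.33, adjusted p = 0.136). St8sia4, a polysialyltransferase, was at -2.03 (SE 0.29, adjusted p = 0.0882), Akr1c14, a hydroxysteroid dehydrogenase, at -2.48 (SE 0.41, adjusted p = 0.156) and Ssu2 at -3.49 (SE 0.56, adjusted p = 0.139), with CS7KO 2 above the other CS7KO libraries (1.92 CPM). Masp1, a protease of the lectin pathway of complement, was at 1.78 (SE 0.27, adjusted p = 0.110), and Hipk2, a nuclear kinase, at 2.45 (SE 0.41, adjusted p = 0.156). On simulated counts with the same means and spread, the test recovered 36 of 100 genes changed 4-fold and 4 of 100 changed 2-fold, so changes of this size could be missed.

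The pathway that Smad7 restrains was read from the genes of TGF-beta signalling and its targets, of which none passed the edgeR test. Tgfb1 stood at -0.58 (SE 0.26, adjusted p = 0.401), its receptor gene Tgfbr1 at 0.57 (SE 0.37, adjusted p = 0.564), and the receptor-activated Smad genes Smad2 at -0.03 (SE 0.24) and Smad3 at 0.26 (SE 0.96) on the log2 scale. Smad3 had 0 counts in CRE 1, and without that library it turned to -0.22. Smad4, the common partner, was at 0.08 (SE 0.24), the repressors Ski and Skil at -0.21 (SE 0.26) and 0.10 (SE 0.31), and Smad6, the other inhibitory Smad, at 0.89 (SE 0.26, adjusted p = 0.291) with 11.2 ± 3.03 CPM in CRE and 20.5 ± 3.90 in CS7KO. Among targets, Ccn2, connective tissue growth factor, had 345 ± 199 CPM in CRE and 773 ± 267 in CS7KO (log2 1.27, SE 0.39, adjusted p = 0.295). The list of TGF-beta responsive genes had 21 members higher and 12 lower with a median of 0.12 and did not pass and was tested as higher (adjusted p = 0.813). The list of pathway components had 16 higher and 12 lower with a median of 0.09, while the test put it lower than other genes (adjusted p = 0.882).

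Genes of the extracellular matrix and its turnover gave no passing gene either. Col1a1 and Col3a1, the main fibrillar collagens of scar, were at 0.35 (SE 0.40) and -0.15 (SE 0.44), Postn, a matricellular protein of activated fibroblasts, at 0.56 (SE 0.55), and Fn1, fibronectin, at -0.14 (SE 0.37) on the log2 scale. The metalloproteinases Mmp2, Mmp9 and Mmp14 were at 1.02 (SE 0.62), 0.76 (SE 1.15) and -0.29 (SE 0.40), and their inhibitor Timp1 at -1.44 (SE 0.56, adjusted p = 0.344). The lists of metalloproteinases (adjusted p = 0.813), matricellular proteins (0.834), other matrix proteases (0.906, with a median of 0.20 and a test of the opposite sign), protease inhibitors (0.503) and collagen processing (0.503) did not pass. Collagens as a list lay lower in CS7KO, with 14 of 22 members lower and a median of -0.14 (adjusted p = 0.0347), and adjusted p = 0.705 with an estimated correlation; Col5a3 at -1.02 (SE 0.28) and Col6a3 at -1.01 (SE 0.28) had the smallest p. That list did not pass without CRE 1 (0.105, median -0.13) or CRE 2 (0.144, median -0.15), and its median turned to 0.056 without CS7KO 2 (0.889) and to 0.014 without CS7KO 4 (0.0841).

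Which groups of genes moved together was asked with lists of cardiac, matrix, metabolic, immune and cell type genes. Compared with all other genes by camera, 21 of 57 lists passed, 12 higher and 9 lower in CS7KO. With a correlation between members estimated from the data, 0 of the 21 passed, 2 of 57 had an unadjusted p under 0.05, and the smallest adjusted p was 0.627. By fry, which tests whether a list moves one way, 0 of 57 passed (smallest adjusted p = 0.143). By fry's test for changes in either direction 4 passed: interferon-stimulated genes, BMP responsive genes and markers of cartilage and bone (adjusted p = 0.0282 each) and titin and sarcomere-associated stress sensing (0.0436).

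Interferon and antigen presentation lists lay lower in CS7KO. Of 32 interferon-stimulated genes, the antiviral genes that interferons switch on, 30 were lower, with a median of -1.03 (adjusted p = 2.4e-13), and adjusted p = 0.627 with an estimated correlation; 0 members passed over all genes in edgeR and 14 passed when adjusted over the list alone, all of them lower. Rsad2, the antiviral enzyme viperin, had 36.2 ± 26.2 CPM in CRE and 6.32 ± 0.635 in CS7KO (log2 -2.35, SE 0.41, adjusted p = 0.156 over all genes), and Trim30a had 30.1 ± 15.4 and 9.78 ± 0.727 CPM; DESeq2 called both over all genes (adjusted p = 1.8e-05 and 0.0057). All 16 tested genes of MHC class II and antigen presentation were lower, with a median of -0.75 (adjusted p = 2.9e-07), and adjusted p = 0.627 with an estimated correlation. Tap1, the peptide transporter, was at -1.18 (SE 0.35) and B2m, the light chain of MHC class I, at -1.04 (SE 0.32) on the log2 scale. The library medians of both lists separated the genotypes (exact permutation p = 0.0286, the smallest the design allows), as those of 6 of 57 lists did (10.5%). The mean over all assignments is 2.86%, and its spread, with lists that move together, was not tested. Interferon-stimulated genes and antigen presentation passed without CRE 1 and CRE 5 (adjusted p = 4.9e-15 and 5.4e-05) and without CRE 3 and CRE 5 (2.8e-08 and 3.4e-07) at the preset correlation. With an estimated correlation neither did, with an adjusted p of 0.729 for both in the first case and of 0.978 for both in the second. DESeq2 also called members of other lists described below, so its calls do not set the interferon genes apart. Among them were Myh7 (DESeq2 adjusted p = 0.0076), Ankrd23 (1.1e-04), Lmod2 (0.0052), Trim63 (9.8e-04), Hk1 (0.0049), Egr3 (0.0022) and Ier2 (0.0051). Acta1 was not called.

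Markers of endothelial cells, fibroblasts and macrophages also lay lower as lists. Of 20 endothelial markers 19 were lower, with a median of -0.86 (adjusted p = 2.9e-07), and adjusted p = 0.627 with an estimated correlation; Tek, the angiopoietin receptor, had 109 ± 47.7 CPM in CRE and 45.6 ± 10.6 in CS7KO, and Ly6c1 586 ± 290 and 185 ± 81.1. The endothelial medians were -0.21, -0.32, 0.97 and 1.33 in CRE 1, 2, 3 and 5, so the 2 CRE libraries with the highest mitochondrial shares carried most of the difference. Without CRE 3 and CRE 5 the list had a median of -0.27 and an adjusted p of 0.0501, or -0.24 and 0.00874 with no term for labelled sex. Fibroblast markers, with 17 of 20 lower and a median of -0.52 (adjusted p = 0.00295), had an adjusted p of 0.634 with an estimated correlation and did not pass without CRE 1 (0.121, median -0.25) or CS7KO 2 (0.217, median -0.32). Macrophage and monocyte markers, with 21 of 25 lower and a median of -0.38 (adjusted p = 0.00445), had an adjusted p of 0.627 with an estimated correlation and did not pass without CRE 1 (0.315, median -0.057) or CS7KO 2 (0.0619, median -0.32).

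Several cardiomyocyte lists lay higher in CS7KO, none of which passed without CRE 3 and CRE 5, a fit with CRE 1 and CRE 2 alone as controls. There the titin, ubiquitin ligase, calcium handling and ion channel lists were still tested as higher, at medians of 0.41, 0.35, 0.25 and 0.37. Genes of hypertrophy and the fetal programme had 16 of 21 members higher and a median of 0.74 (adjusted p = 0.00140), ventricular sarcomere genes 17 of 22 higher with 0.64 (1.2e-04), and titin and sarcomere-associated stress sensing 17 of 19 higher with 0.76 (2.0e-05); each had an adjusted p of 0.627 with an estimated correlation. The hypertrophy medians of CRE 1 and CRE 2 (0.38 and 0.47) lay above those of CS7KO 2, 3 and 4 (0.24, 0.016 and 0.17), so CRE 3 and CRE 5 (-0.91 and -1.29) carried the difference. Without these libraries the tests of the hypertrophy and ventricular sarcomere lists turned to lower, with medians still above 0 (0.17 and 0.082; adjusted p = 0.904 and 0.839). Myh7, the beta myosin heavy chain re-expressed under load, had 662 ± 644 CPM in CRE and 2743 ± 1176 in CS7KO (log2 2.15, SE 0.65, adjusted p = 0.292), Nppa, which encodes atrial natriuretic peptide, 1024 ± 821 and 2301 ± 297 CPM (log2 1.60, SE 0.63, adjusted p = 0.352), and Nppb 946 ± 620 and 1781 ± 532 CPM (log2 1.17, SE 0.44, adjusted p = 0.337). Acta1, skeletal alpha actin, was at -0.02 (SE 0.53) and Myh6, the adult alpha myosin, at 0.95 (SE 0.44). Ankrd23 had 16.1 ± 14.4 and 71.1 ± 13.1 CPM and Lmod2, a regulator of thin filament length, 323 ± 214 and 1058 ± 323 CPM. Ubiquitin ligases and atrophy genes had 15 of 16 members higher and a median of 0.53 (adjusted p = 1.0e-05; 0.627 with an estimated correlation), among them Trim63, which encodes MuRF1, with 53.96 ± 25.99 and 181.2 ± 62.7 CPM; 4 members passed when adjusted over the list alone. Calcium handling genes, with 15 of 23 higher and a median of 0.51 (adjusted p = 0.00974), and cardiac ion channels, with 20 of 26 higher and 0.47 (0.0254), both had an adjusted p of 0.627 with an estimated correlation. The ion channel list did not pass without CRE 3 (0.0742), CRE 5 (0.073), CS7KO 2 (0.0708) or CS7KO 4 (0.089), at medians of 0.59, 0.51, 0.35 and 0.39, nor the calcium handling list without CRE 5 (0.067, median 0.40).

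Several energy metabolism lists lay higher as well, while nuclear-encoded oxidative phosphorylation, with 28 of 43 members lower and a median of -0.21, did not pass and was tested as higher (adjusted p = 0.813). TCA cycle genes had 19 of 20 members higher and a median of 0.79 (adjusted p = 4.5e-07; 0.627 with an estimated correlation). Glycolysis and glucose uptake had 24 of 28 higher and a median of 0.68 (1.9e-05; 0.627 with an estimated correlation), with hexokinase Hk1 at 128 ± 58.6 CPM in CRE and 293 ± 20.2 in CS7KO. Fatty acid uptake and oxidation had 29 of 38 higher and 0.34 (0.00113), and ketone and branched-chain amino acid metabolism 17 of 20 higher and 0.59 (0.00121), both with an adjusted p of 0.634 with an estimated correlation. Hypoxia responsive genes had 15 of 21 higher and 0.68 (0.00882; 0.627 with an estimated correlation), and autophagy and lysosome genes 15 of 22 higher and 0.27 (0.0399; 0.634 with an estimated correlation). All 13 mitochondrially encoded genes were lower, with a median of -0.78 (0.0254; 0.705 with an estimated correlation), and mt-Nd3, a subunit of complex I, had 1703 ± 2191 CPM in CRE and 315 ± 108 in CS7KO. The mitochondrially encoded medians of CRE 1 and CRE 2 (-0.98 and -0.66) lay below those of every CS7KO library (-0.53 to -0.13), and those of CRE 3 and CRE 5 (0.74 and 2.40) above them. The median of the fatty acid list was -1.68 in CRE 5, the library with 69.8% mitochondrial counts, against 0.09 to 0.26 in the other CRE libraries. Without CRE 5 that list no longer passed (adjusted p = 0.410, median 0.09), nor did the ketone list (0.067, median 0.34). The mitochondrially encoded list did not pass without CRE 5 (0.438), CS7KO 3 (0.2003) or CS7KO 4 (0.119), with medians of -0.20, -0.33 and -0.46, nor the hypoxia list without CS7KO 3 (0.0799, median 0.37). Without CRE 3 and CRE 5 the mitochondrially encoded list turned to a median of 0.40 (adjusted p = 0.383). The tests of the TCA cycle, fatty acid, ketone and autophagy lists turned to lower with none of them passing (medians -0.0021, 0.16, 0.011 and -0.26), the fatty acid list only with a term for labelled sex. Nuclear-encoded oxidative phosphorylation then passed as lower (median -0.96, adjusted p = 5.5e-14; 0.978 with an estimated correlation), with library medians of 1.40 in CRE 1 and -0.088 in CRE 2. The autophagy list did not pass without CRE 2 (0.108), CRE 3 (0.157), CRE 5 (0.330), CS7KO 3 (0.146) or CS7KO 4 (0.197), with medians of 0.25, 0.30, 0.011, 0.18 and 0.17.

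Without CRE 3 and CRE 5, the libraries with the largest mitochondrial shares, none of the 12 lists that lay higher passed, and 5 of the 21 lists kept their call and direction (7 with no term for labelled sex). Without CRE 1 and CRE 5, 19 of 21 did (18 with no such term). Both fits kept as many control libraries, so their number alone does not account for the calls lost without CRE 3 and CRE 5. In the fit without CRE 3 and CRE 5 the medians of some lists stayed well above 0: ion channels (0.47 to 0.37), ubiquitin ligases (0.53 to 0.35), hypoxia (0.68 to 0.41) and titin (0.76 to 0.41). Others lost most of theirs, such as glycolysis (0.68 to 0.13) and the TCA cycle (0.79 to -0.0021), and the tests of 8 of the 21 lists turned.

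**Figure D4:**
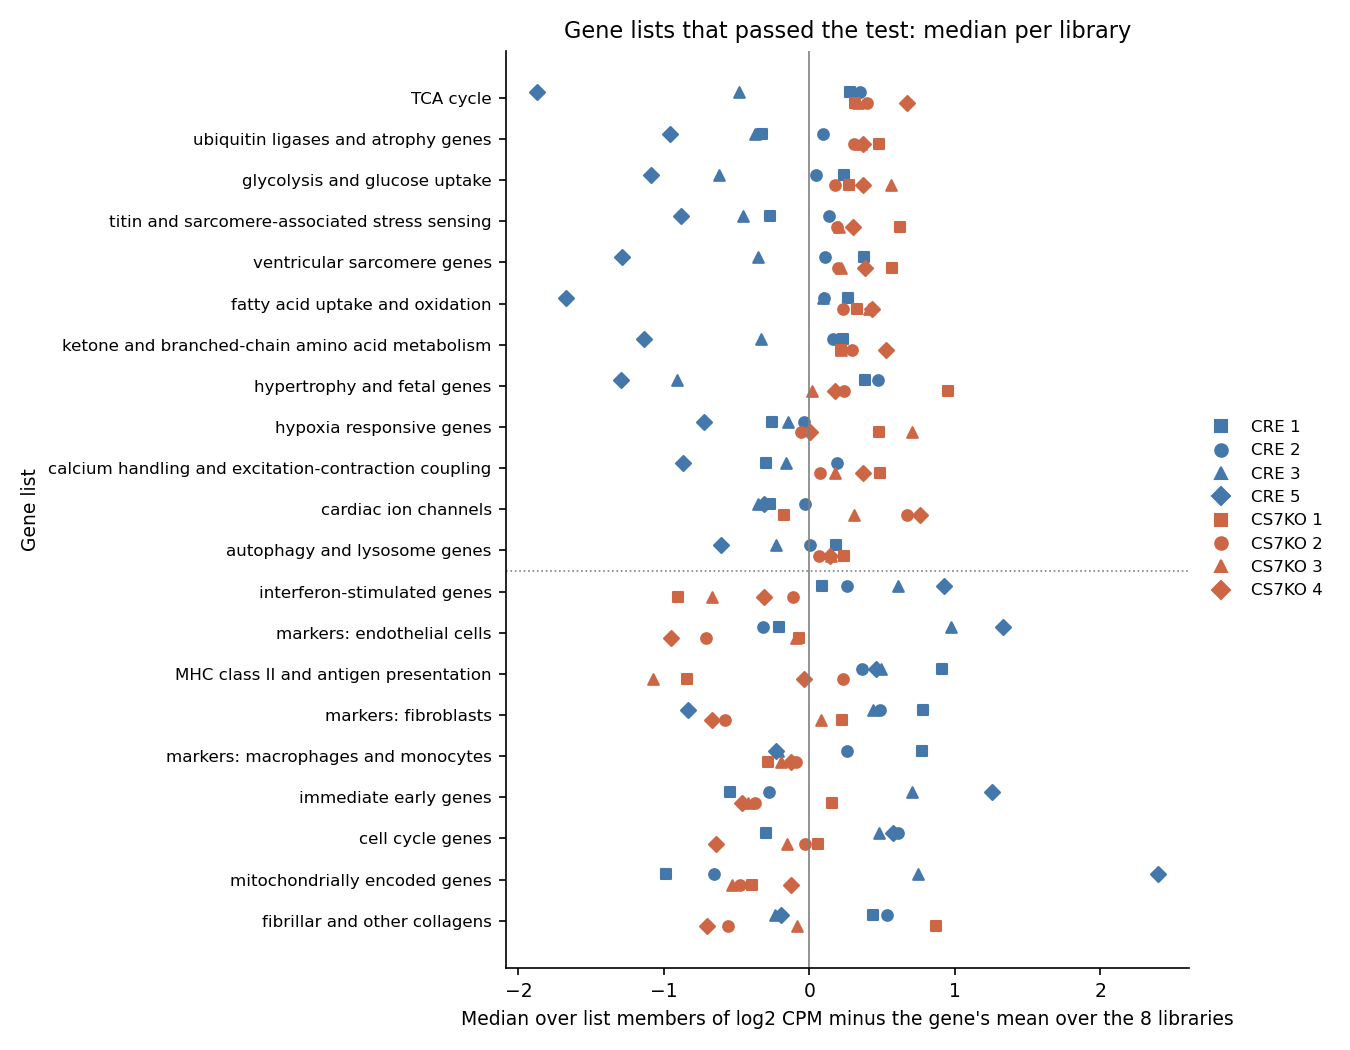
Each point is the median, over the members of a list that passed the test, of a gene's log2 CPM minus its mean over the 8 libraries, for CRE (blue) and CS7KO (orange) libraries with 1 marker shape per library. Lists above the dotted line lay higher and those below it lower in CS7KO; CRE 5 (blue diamonds) is the lowest point in most metabolic lists, for example -1.68 for fatty acid uptake and oxidation.

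Among the remaining called lists, proliferation and immediate early genes lay lower. Cell cycle genes had 25 of 30 members lower and a median of -0.63 (adjusted p = 0.00882; 0.627 with an estimated correlation), with the topoisomerase Top2a at 4.46 ± 1.97 CPM in CRE and 1.59 ± 0.855 in CS7KO and cyclin B1, Ccnb1, at 2.50 ± 0.974 and 0.601 ± 0.394. The list's median was -0.30 in CRE 1, against 0.48 to 0.61 in the other CRE libraries. Pttg1, a cell cycle gene outside that list, went the other way. Immediate early genes, which respond within minutes to stimulation, had 16 of 23 lower and a median of -0.42 (adjusted p = 0.00882; 0.645 with an estimated correlation), with Egr3 at 8.11 ± 5.28 and 1.89 ± 0.514 CPM and Ier2 at 63.0 ± 41.3 and 16.4 ± 2.41 CPM. Its median was 0.16 in CS7KO 1, against -0.47 to -0.37 in the other CS7KO libraries, and without CRE 5 the list had a median of -0.099 and an adjusted p of 0.113. The medians of CRE 1 and CRE 2 were -0.54 and -0.28, and those of CRE 3 and CRE 5 0.71 and 1.26. Without CRE 3 and CRE 5 the list turned to a median of 0.32 (adjusted p = 0.772), or 0.084 with no term for labelled sex, where the test stayed lower (0.766).

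The labels give both sexes, and the Y-linked genes were read in every library to check them. Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, summed to 199 ± 9.99 CPM in the 4 libraries labelled female and to 191 ± 44.1 CPM in the 4 labelled male. Xist, the RNA that silences the second X chromosome in females, had between 0 and 36 counts per library and at most 1.03 CPM. The libraries labelled female thus carried Y-linked RNA at the level of those labelled male, and below they are called by their labels alone. Between the labelled sexes 0 of 16002 genes passed edgeR's test and 0 passed with DESeq2, while 427 had an unadjusted p under 0.05 and the smallest adjusted p was 0.823.

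**Figure D5:**
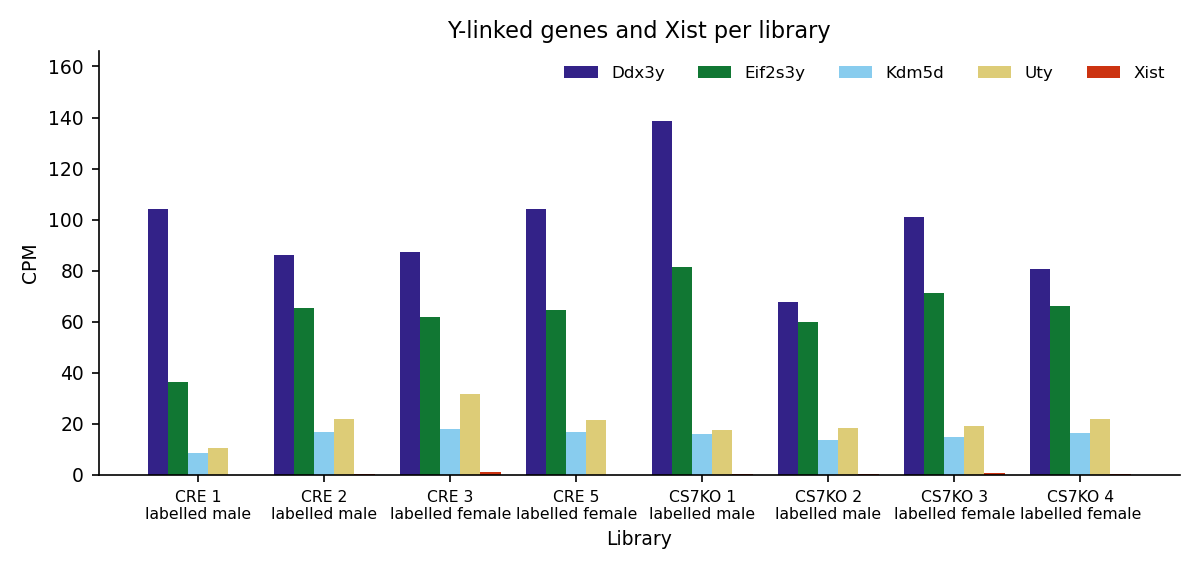
Bars give CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and of Xist in each library, with the labelled sex under its name. The libraries labelled female show the Y-linked genes (summed mean 199 CPM) as those labelled male do (191 CPM), and Xist reaches at most 1.03 CPM.

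Whether the loss of Smad7 acted differently in the labelled sexes was tested by the interaction of genotype and label, and 0 genes passed edgeR's test (1133 with an unadjusted p under 0.05, smallest adjusted p 0.234). The gene with the smallest p was Myh11, the smooth muscle myosin heavy chain, with a log2 fold change of 0.93 in libraries labelled male and -2.62 in those labelled female (difference 3.55, SE 0.44, adjusted p = 0.234). Slc26a10 had 0.26 and -2.68, and Tcim, a regulator of Wnt signalling, 0.46 and -2.97 (adjusted p = 0.667 for both). Myh11 stood at 137 and 150 CPM in CRE 3 and CRE 5 and between 17.1 and 37.2 CPM in the other 6 libraries. DESeq2 gave 44 genes, and edgeR without CRE 2 gave 1476, a fit in which the lone CRE library labelled male is assumed to vary like the other groups. Given the Y-linked counts, no difference between sexes can be read from these values.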

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

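The tests of near-identical copies, of a sequence variant, of the Y-linked genes, of pairs of libraries left out, of pseudogenes as a class and of the cardiomyocyte share were chosen only after the result was seen; those of other splits of the libraries and of chromosome segments were planned. Among 132 groups of 4 libraries checked for a library far from the other 3, 5 held one, and chance gives about 6.6. Smad3, a transducer of TGF-beta signals, stood at -3.611 log2 CPM in CRE 1, where it had no counts, against 3.682 to 3.992 in the other CRE libraries. Ssu2 stood at 1.003 log2 CPM in CS7KO 2, against -0.1131 to 0.03649 in the other CS7KO libraries. The median of the list for fatty acid uptake and oxidation was -1.676 in CRE 5, against 0.09 to 0.2636 in the other CRE libraries. Immediate early genes had a median of 0.1564 in CS7KO 1, against -0.4665 to -0.3731 in the other CS7KO libraries, and cell cycle genes had -0.2987 in CRE 1, against 0.4752 to 0.6073 in the other CRE libraries.

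The first pattern is the set of 6 genes that differed between CS7KO and CRE. Of 34 splits of the libraries that could be fitted, the real one gave 6 genes in edgeR and the others at most 0. This is the least share that 34 splits can give, so it speaks against chance for that count without excluding it. The count includes the 4 pseudogenes, and with families summed the real split gave 0 genes, so the splits decide nothing for Pttg1 or Cyfip2 alone. At an unadjusted p under 0.05 the real split gave 2022 genes. The split of CRE 1, CRE 3, CS7KO 3 and CS7KO 4 against the rest gave 2686. With DESeq2, 2 of the 34 splits gave as many as the real 503, and the other, which set CRE 1, CRE 3, CS7KO 3 and CS7KO 4 against the rest, gave 1885, which points to a structure of the samples; chance cannot be excluded there. For Cyfip2 the tables argue against shared reads, since the closest stretch of any other annotated gene over 100 bases had 83.6% identity; for Pttg1 they stay open, as no other gene aligned over 100 bases but 70 bases (4.2% of the transcript) matched Tcf4 at 97.1%, and the read length is not given in the sources used here. An inherited chromosome segment around Pttg1 and Cyfip2 stays open, because 10.96% of their 73 tested neighbours had an unadjusted p under 0.05, below the 12% median of random windows but within their spread of 5.33% to 22.7% (a share of 0.564 of the windows had as many), as does an effect of the Smad7 deletion itself.

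For the 4 pseudogenes in that set, shared reads are a candidate explanation, since the lowest identity to a protein-coding parent was 97.4% and each fold change lay outside the interval of its summed family. A fixed sequence difference between the lines in reads of Rplp0 and Rps3a1 may be what moves those reads for Gm8730, Gm9625 and Rps3a2: the share of Gm8730 varied by 5.99% of its mean in CRE while the Rplp0 count varied by 53.1%, and Rps3a2 varied by 4.49% in CS7KO against 9.55% for Rps3a1. A first form of this test used CRE alone, where Rps3a2 is near background and varied by 33.6% against 39.9%, which had left the question open; it was changed after that was seen. An alignment or read length that differed between the genotypes stays open: 13.6% of pseudogenes and 12.6% of other genes had an unadjusted p under 0.05 (1-sided Fisher exact p = 0.246), whereas the form it replaced after the result was seen, on the passing genes themselves, gave 4 pseudogenes of 6 against 4.05% of the tested genes (exact p = 3.7e-05). Any difference in background between the mouse lines goes together with the genotype, so it is confounded with the deletion; the labels give the strain as C56BL and name no substrain.

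The next pattern is Y-linked RNA in the libraries labelled female. The sum of Ddx3y, Eif2s3y, Kdm5d and Uty in them was 1.04 times that in the libraries labelled male. Labels that do not match the animals may explain this. Each library labelled female had a sum between 185 and 207 CPM, within the 160 to 253 CPM of those labelled male. These values argue against the label female for the 4 libraries that carry it. The tables argue against RNA of male hearts mixed into libraries of female hearts, as the lowest Xist level in the libraries labelled female was 0 CPM and the highest in any library was 1.03 CPM. Between the labelled sexes all 34 splits gave as many genes as the real one, with 0 against at most 1, which a real count of 0 makes certain, so the splits decide nothing here; no biological explanation was tested.

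The last pattern is the gene lists that differed between CS7KO and CRE: of the 34 splits, 13 gave as many, with 21 for the real one and up to 34 for the others, so chance cannot be excluded for this count, and with an estimated correlation 0 lists passed in all 8 libraries or without either pair below. At the preset correlation the tables argue against CRE 1 and CRE 5 standing apart as the whole cause. Without them 19 of the 21 lists kept call and direction (18 with no term for labelled sex). CRE 3 and CRE 5 standing apart may explain part of it, as 5 of the 21 did without these (7 with no such term). CRE 3 and CRE 5 are also the CRE libraries labelled female, so that with the term the fit then rests on the libraries labelled male. It leaves CRE 1 and CRE 2 as the only controls, and CRE 1 had the lowest quality weight of the 8 libraries (0.123). Lost calls can thus also come from CRE 1. The number of libraries alone does not account for them, as leaving out CRE 1 and CRE 5 removed as many. Some lists lost their call but kept much of their median, such as ion channels (0.47 to 0.37) and cell cycle genes (-0.63 to -0.42). The tests of 8 of the 21 turned. Interferon-stimulated genes, MHC class II and antigen presentation, and fibroblast markers kept call and direction without either pair. The fibroblast list, though, did not pass without CRE 1 alone (camera adjusted p = 0.121) or CS7KO 2 alone (0.217). A larger share of cardiomyocyte RNA in CS7KO libraries stays open, as does an effect of the deletion: the erythroid markers parted from the endothelial markers with an exact permutation p of 0.0286, which by a first criterion would have argued against it, but adjustment over the marker lists makes this 0.229, the least that a single list can reach in this design, so the test decides nothing.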

How the results depend on the processing

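The alternatives without CRE 1 and CRE 5, without CRE 3 and CRE 5, with sample quality weights, without the sex term and either pair, and with the same 6 libraries as the block were tests chosen only after the result was seen. Of the comparisons' values, 76 stayed the same and 19 counts moved. The 76 include the 26 values of Smad7, which were judged by threshold and sign. The rest of the 76 are counts that stayed within 1.5 times. Of the other named genes' values, 867 kept their side of the threshold, 60 newly passed and 28 no longer did. Among the 867, 41 values in 11 genes had the opposite sign, none of them passing. Of the lists' values 903 kept their side (109 with a median of opposite sign), 39 newly passed and 116 no longer did. In another 22 the direction of the test reversed, where the list passed in the main setting, in the alternative or in both. Genes between CS7KO and CRE numbered 6, and 503 with DESeq2, 338 with no filter, 0 among protein-coding genes, 16 without CRE 1 and CRE 5, 3 without CRE 3 and CRE 5, 3218 with sample quality weights, which gave CRE 1 a weight of 0.123 and CS7KO 3 one of 5.21, and 26 without the sex term and CRE 1 and CRE 5; leaving out 1 library gave 3 (without CS7KO 3) to 14 (without CRE 1). The 6 genes were among those called with DESeq2, with no filter and with quality weights. Smad7 ranged from -0.81 to -0.19 over 26 alternatives and passed in none. Lists numbered 21, and 11 with a block for replicate number, 12 in the same 6 libraries without it, 0 with an estimated correlation, 0 by fry's test of 1 direction, 7 without CRE 3 and CRE 5, and 12 without these and the sex term; leaving out 1 library gave 16 to 24. The numbers do not pair the samples, as same-number correlations were 0.04, -0.09 and 0.35. Interaction genes numbered 0 in edgeR, 44 with DESeq2 and 48 with no filter, and 0 to 1476 (without CRE 2) with 1 library left out; genes between labelled sexes numbered 0 and, with no filter, 7. The list of nuclear-encoded oxidative phosphorylation, tested as higher though its median was -0.21, reversed to lower with medians of -0.53 with the block, -0.63 in the same 6 libraries, -0.53 without CRE 5 and -0.96 without CRE 3 and CRE 5; with 1 library left out its median ranged from -0.53 (without CRE 5) to 0.41 (without CRE 1). Mitochondrially encoded genes reversed in the test with the block (median -0.13) and, with 0.40, without CRE 3 and CRE 5. Without these 2 libraries the test also reversed for immediate early genes (0.32), hypertrophy and fetal genes (0.17), ventricular sarcomere genes (0.082), autophagy (-0.26), fatty acid oxidation (0.16), the TCA cycle (-0.0021) and ketone metabolism (0.011). With the sex term dropped too, it reversed for nuclear-encoded oxidative phosphorylation (-0.89), mitochondrially encoded genes (0.45), hypertrophy and fetal genes (0.026), ventricular sarcomere genes (0.076), autophagy (-0.14), the TCA cycle (0.087), ketone metabolism (0.018), matricellular proteins (-0.37) and heat shock proteins (-0.22). Fewer libraries or genes enter several of these; otherwise the cause was not tested.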

Other observations

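The test of neighbouring pairs was planned, and the tests and values of genes outside the rule for named genes were chosen only after the result was seen. Several gene groups that the comparisons above do not describe gave no passing list by camera. Beta-adrenergic and angiotensin signalling, the neurohormonal drive of the loaded heart, had a median log2 fold change of 0.24 (camera adjusted p = 0.0697), ErbB and EGF ligands and receptors 0.33 (0.212), and the unfolded protein response 0.20 (0.106). BMP responsive genes, the other arm that inhibitory Smads restrain, had 9 of 12 members lower with a median of -0.45 (0.137). Inflammatory cytokines and chemokines stood at -0.33 (0.0941), apoptosis genes at -0.21 (0.192), p53 targets at 0.42 (0.184), complement and acute phase genes at 0.33 (0.158) and circadian clock genes at 0.32 (0.974). Heat shock proteins had a median of 0.09 and a mean of -0.07 (0.503). NRF2 targets had a median of 0.02 and nuclear-encoded oxidative phosphorylation one of -0.21, and the test gave each the opposite sign (0.834 and 0.813).

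Markers of other cell types also gave values and no list that passed by camera. Epicardial markers had 12 of 13 members higher with a median of 0.44 (adjusted p = 0.344), activated fibroblasts stood at 0.28 (0.503), lymphatic endothelium at 0.37 (0.503) and atrial cardiomyocytes at 0.53 (0.486). Mural cells stood at -0.30 (0.135), B and plasma cells at -0.54 (0.122), T and NK cells at -0.15 (0.763) and mast cells at -0.40 (0.486). Erythroid cells were at 0.28 (0.633), platelets at -1.05 (0.221) and neutrophils at 0.76 (0.813). Adipocytes were at 0.13 (0.882, with a test of the opposite sign), Schwann cells and neurons at -0.09 (0.813), skeletal muscle at -0.28 (0.834), and cartilage and bone at -0.30 (0.344). Conduction system markers had a median of -0.04 and a mean of 0.13 (0.807).

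Transfer RNAs of the mitochondrion took 0.719% of the counts in CRE 1 and between 0.0487% and 0.149% in the other libraries. Rpl30, the parent gene of Rpl30-ps10, had 316, 98.6, 253 and 96.3 CPM in CRE 1, 2, 3 and 5 and 34.0, 32.8, 4.16 and 3.36 CPM in CS7KO 1 to 4 (log2 -4.06, edgeR adjusted p = 0.173), with its summed family at -1.16. Inherited segments that differ between the lines, over the genome, stay open: the 100 genes with the smallest p held 9 pairs within 1 Mb of each other against a median of 8 in random draws, and a share of 0.413 of the draws held as many.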
